A study of Homo sapiens with 4 samples.

How the data were processed

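Poly(A)-selected RNA of 22Rv1 cells, a line derived from castration-resistant prostate cancer, was sequenced after 12 h with 40 nM JMC45, a compound the submitters describe as a CDK9 degrader, or with the DMSO vehicle. The series title and design call the compound D45, which was taken to be the same one. The labels name 2 libraries per group. The deposited values are TPM, a length-scaled share of each library, for each Ensembl gene in each library, per the file headers. The submitters' processing notes name fastp, HISAT2 and StringTie, without versions or roles. The genome build and the annotation are not given in the sources used here, so no coordinates are printed. The library kit was a stranded one with oligo(dT) selection, per the labels' protocols. Whether strand was used in the quantification is not given in the sources used here, so antisense genes and genes with near-identical copies are treated as uncertain.

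TPM keeps no sequencing depth, so the depth of each library is unknown, and no counting intervals or floors are given. TPM is also relative: when a few abundant transcripts take a larger share of a library, all others take a smaller one. No spike-in was analysed here, so the values cannot show whether the total amount of mRNA per cell changed. A fold change is therefore a change in a transcript's share of its library.

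The table held 63241 genes and 50 further lines without values, which were left out. Of the gene identifiers, 62666 were matched to a symbol and 575 were not. 32141 genes were listed at 0 in all 4 libraries. Gene type, exonic length and number of exons were taken from GENCODE release 29 as properties only, and 13475 of the 14018 tested genes had an entry there. The 2 control columns were assigned to the vehicle libraries by their names and numbers.

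Values were tested as log2(TPM + 1) for the 14018 genes with a mean TPM of at least 1 over the 4 libraries. This scale understates the change of genes with low TPM. The test was limma 3.58.1 in R 4.3.3, two-sided, with an intensity trend in the empirical Bayes step and no replicate block. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and "rose" and "fell" are used only for genes that passed it. Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, which compares a list's members with all other genes, and adjusted over the 32 lists with at least 5 tested members. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list's members move one way on balance, without comparing them with other genes. Shares of TPM were compared by a two-sided exact permutation test, which cannot go below p = 0.33 with 2 libraries against 2. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

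The comparison, the tests, 34 gene lists, 12 alternative settings and the rule for naming genes were fixed before the data were examined. The rule named 8 preset genes, among them CDK9, CCNT1, CCNT2, HEXIM1, MYC, MCL1 and KLK3. A few genes that the rule named are not reported here. It also named the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with a mean TPM of at least 5, both JMC45 libraries on one side of both vehicle libraries, and an assigned symbol that is not a pseudogene, clone name or bare identifier. Symbols such as U2, a family name carried by several entries, were not taken as assigned, a detail settled after the values were seen. In each list, the members named were up to 4 of those with the largest absolute change past the threshold. Members that moved against the rest of their list, where few did, and the genes of the closing observations were chosen after their values were seen.

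The alternatives were a pseudocount of 0.1, no filter on low values, a mean TPM of at least 5, median-of-ratios scaling, quantile normalization, TPM recomputed without the mitochondrially encoded genes, no intensity trend, the replicate number as a block, and each library left out in turn. One alternative was added after seeing the data, in which the summed TPM of the mitochondrially encoded genes was held equal in all libraries. The filter used the deposited TPM under every scaling.

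The gene test was tested on simulated data for the JMC45 and vehicle comparison with 14018 genes, in which 200 genes were changed. It recovered 10% of the 50 genes changed by 0.5 on the log2 scale, 76% of those changed by 1, 100% of those changed by 2 and 98% of those changed by 3. Of its calls, 1.39% were genes that had not been changed. In a second simulation of the same comparison, camera gave p = 1.8e-92 for a shifted list of 40 genes and p = 0.711 for an unshifted list of 40, and with an estimated correlation the values were p = 0.0017 and p = 0.705. Both simulations drew noise independently for each gene and had no general shift. In the data the median gene changed by -1.10, and the estimated correlation was 0.665 in the ribosomal protein list. The simulations therefore cannot show the error rates of either test under such conditions.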

Results

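The transcriptome of 22Rv1 cells was measured by RNA sequencing after 12 h with 40 nM JMC45 or with vehicle. CDK9 is the kinase of P-TEFb, the complex that releases paused RNA polymerase II into productive elongation, and the comparison asked which transcripts differed when the cells were exposed to a compound targeting it. There were 2 libraries per group, and the labels do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Log2 TPM correlated at r = 0.984 across genes between the vehicle libraries and at r = 0.985 between the JMC45 libraries, against 0.892 to 0.900 between groups. The depth of the libraries is unknown.

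Most transcripts took a smaller share of the library after JMC45, while ribosomal protein and mitochondrially encoded transcripts took a larger one. The vehicle libraries had 15295 and 14875 genes at a TPM of at least 1, and the JMC45 libraries had 11821 and 11629. Cytosolic ribosomal protein genes took 19.4% ± 1.17 (SD, n = 2) of all TPM in vehicle and 29.2% ± 1.13 in JMC45. Mitochondrially encoded genes took 20.3% ± 0.225 and 28.0% ± 1.90, and replication-dependent histone genes took 0.0178% ± 0.000212 in vehicle and 0.0142% in both JMC45 libraries. The 100 most abundant genes held 44.9% ± 1.12 of vehicle TPM and 63.6% ± 0.926 of JMC45 TPM. For each of these shares the 2 groups did not overlap, and the exact permutation test gave p = 0.33, the smallest value it can give here.

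Of 14018 genes tested, limma called 596 higher and 11311 lower in JMC45, of which 117 were at least 2-fold higher and 7612 at least 2-fold lower on the log2(TPM + 1) scale. The median gene changed by -1.10 on the log2 scale. That shift rests on the scaling: the median was -0.02 after median-of-ratios scaling, 0.02 after quantile normalization, -1.04 with the mitochondrially encoded genes left out and -1.47 with their total held equal. Median-of-ratios scaling called 4888 genes higher and 4981 lower, quantile normalization 4716 higher and 4603 lower, and holding the mitochondrially encoded total equal gave 181 higher and 12685 lower. All 596 increases were also called higher after median-of-ratios scaling, whereas 4981 of the 11311 decreases were still called lower there and 2552 were called higher. That scaling gives each library 1 factor, which raised the changes of genes in general, as from 1.12 to 2.47 for RPS29. Increases on TPM could hardly be lost there and decreases had to be, so the contrast does not show which direction is more reliable. Because the direction of many genes depends on the scaling, the calls after median-of-ratios scaling are given beside those on TPM for each list below. Among 11478 nuclear protein-coding genes outside the ribosome, 330 rose and 9682 fell.

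**Figure D1:**
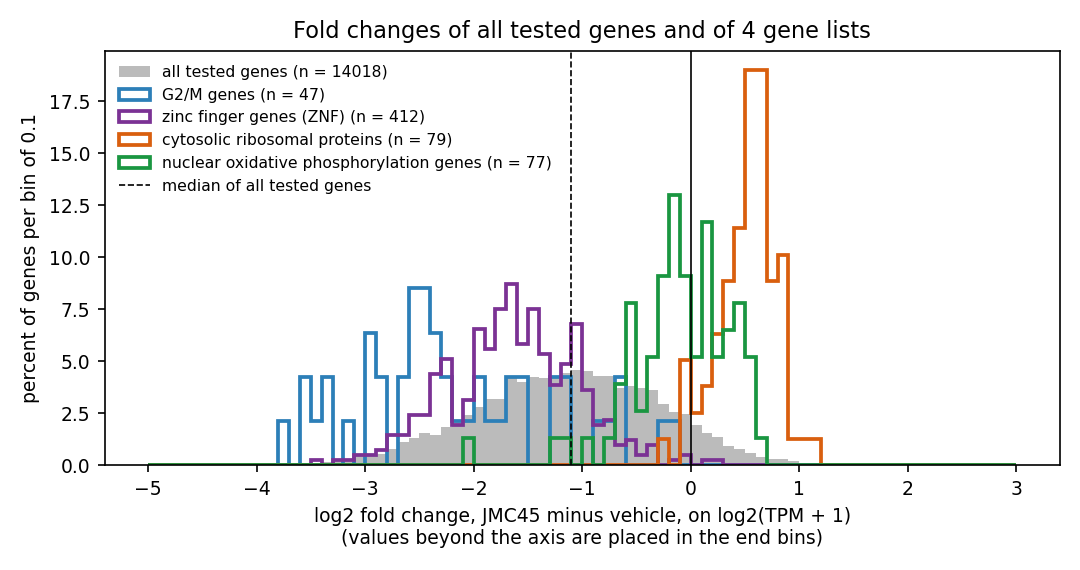
Distribution of log2 fold changes (x axis, JMC45 minus vehicle on log2(TPM + 1); y axis, percent of genes per bin) for all tested genes and 4 gene lists. The dashed line marks the all-gene median of -1.10; G2/M genes (median -2.34) and zinc finger genes (median -1.64) lie below it, while ribosomal protein genes (median 0.55, and 0.11 after quantile normalization) and nuclear oxidative phosphorylation genes (median -0.05, and 1.30 after median-of-ratios scaling) lie above it.

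CDK9 mRNA (ENSG00000136807) itself was lower in JMC45. It measured 21.3 ± 1.63 TPM in vehicle and 4.36 ± 0.813 TPM in JMC45 (SD, n = 2), a log2 change of -2.06 (SE 0.14, limma adjusted p = 3.85e-05), and -0.86 after median-of-ratios scaling. Because the compound is described as acting on the protein, the mRNA does not check the labels. All 29 tested genes of P-TEFb and elongation control fell on the TPM scale, with a median of -1.75, or -0.65 relative to all genes, and after median-of-ratios scaling 19 fell and 3 rose. The largest decrease among all named genes on the log2(TPM + 1) scale was that of MEPCE, the capping enzyme of 7SK RNA, from 67.9 ± 1.82 to 1.82 ± 0.276 TPM (log2 change -4.62). As a ratio of mean TPM the decreases of PPP1R10 (58.9-fold) and GPANK1 (49.95-fold), from lower levels, were larger than that of MEPCE (37.39-fold). HEXIM1 and HEXIM2, which hold P-TEFb inactive on 7SK, fell by 2.90 and 2.59 on the log2 scale, and LEO1, a PAF1 complex subunit, fell by 3.12. The cyclin CCNT1 fell by 1.75, while CCNT2 fell by 0.93 on TPM and had a value of 0.16 after median-of-ratios scaling and 0.40 after quantile normalization. Camera placed the list below other genes (adjusted p = 0.0109), with adjusted p = 0.613 with an estimated correlation.

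Most members of the other lists of transcription, splicing and protein turnover fell on TPM, but not of every list after median-of-ratios scaling. Of 20 other cyclin-dependent kinase genes, 18 fell on TPM, led by CDK17 (log2 change -2.74) and CDK7, the TFIIH kinase (-2.58), but after median-of-ratios scaling 6 fell and 9 rose. Of 12 RNA polymerase II subunit genes, 9 fell on TPM, and after median-of-ratios scaling 2 fell and 7 rose. The large subunit POLR2A (-2.29, and -1.01 after median-of-ratios scaling) and POLR2D (-1.78, and -0.66) led the decreases. Camera called neither list (adjusted p = 0.413 and 0.687) except without the filter on low values, where both lay below other genes (adjusted p = 0.00243 and 0.0188). In that setting the comparison was with 31100 genes whose median was -0.30 rather than -1.10. The RNA polymerase II list thereby went from 0.35 to -0.45 relative to all genes. The same background holds for the other lists below that are called in that setting. Zinc finger genes of the ZNF family fell in 402 of 412 cases on TPM, with a median of -1.64, and after median-of-ratios scaling 288 fell and 23 rose. ZNF740 (-3.46) and ZNF282 (-3.22) had the largest changes. Their camera call (adjusted p = 0.000405) had adjusted p = 0.689 with an estimated correlation. Of 32 genes for SR proteins and hnRNPs, which direct splicing, 30 fell on TPM, but after median-of-ratios scaling 12 fell and 12 rose. The splicing factor SRSF3 went from 453.8 ± 43.2 to 27.6 ± 0.113 TPM (log2 change -3.99) and HNRNPDL from 305.3 ± 14.2 to 17.3 ± 0.537 TPM (-4.07). Camera's call for this list (adjusted p = 0.0217) had adjusted p = 0.668 with an estimated correlation and turned direction under median-of-ratios scaling. It was also lost at a mean TPM of at least 5 (adjusted p = 0.0857), with the mitochondrially encoded genes left out (0.0524) and without the intensity trend (0.182). Of 16 cullin ligase components, the machinery through which many degraders act, 14 fell on TPM, with CAND1 at -2.31 and CUL2 at -2.28, while after median-of-ratios scaling 6 fell and 5 rose. Camera did not call that list (adjusted p = 0.209) except without the filter on low values, where it lay below other genes (adjusted p = 0.00131).

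Genes of mitosis lay furthest below the general shift. Of 47 G2/M genes 46 fell on TPM, with a median of -2.34, or -1.24 relative to all genes, and after median-of-ratios scaling 34 fell and 6 rose. The mitotic kinase AURKB went from 84.0 ± 0.120 to 5.34 ± 0.170 TPM (log2 change -3.75), AURKA from 62.2 ± 0.658 to 4.41 ± 0.212 TPM (-3.55), and CDC20, an activator of the anaphase-promoting complex, fell by 3.52. Of 47 genes of G1/S and DNA replication 46 fell, 47 adjusted over the list alone, with a median of -1.71, and after median-of-ratios scaling 27 fell and 7 rose. The cyclin CCNE2 went from 43.3 ± 7.01 to 1.80 ± 0.0283 TPM (-3.98), the primase PRIM1 from 67.9 ± 0.474 to 3.99 ± 0.438 TPM (-3.79), and the origin licensing factor CDC6 from 73.0 ± 2.98 to 4.46 ± 0.248 TPM (-3.76). GINS3, part of the replicative helicase, fell by 3.48. Camera placed both lists below other genes (adjusted p = 8.42e-06 and 4.44e-05), each with adjusted p = 0.516 with an estimated correlation. In homologous recombination and the Fanconi pathway, 35 of 36 genes fell on TPM, with a median of -1.81, and after median-of-ratios scaling 22 fell and 4 rose. ATRIP (-3.24), the exonuclease EXO1 (-2.87) and BRCA1 (-2.64) led them. FANCA, singled out after its value was seen, rose from 27.6 ± 2.12 to 34.6 ± 3.22 TPM, and its log2 change of 0.31 became -0.13 with the mitochondrially encoded total held equal and was not called without vehicle replicate 1 (0.24) or without JMC45 replicate 1 (0.22). The list's camera call (adjusted p = 0.0199) had adjusted p = 0.627 with an estimated correlation and was lost at a mean TPM of at least 5 (adjusted p = 0.0877).

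MYC, a short-lived transcription factor, went from 96.8 ± 5.08 to 14.6 ± 0.919 TPM, a log2 change of -2.65 (SE 0.08, limma adjusted p = 9.82e-06), and -1.34 after median-of-ratios scaling. Of 58 MYC target genes, a list that holds ribosome biogenesis genes and others, 57 fell on TPM, with a median of -1.72, and after median-of-ratios scaling 34 fell and 13 rose. The members with the largest decreases were PLK4, a centriole duplication kinase (-3.58), the tRNA ligase subunit FARSA (-3.27), and the ribosome assembly factors GRWD1 (-3.09) and NOP16 (-3.06). Camera gave adjusted p = 6.04e-05 for the list and adjusted p = 0.466 with an estimated correlation. Of 33 immediate early genes 27 fell on TPM and 3 rose, and after median-of-ratios scaling 17 fell and 8 rose. ZFP36L2, an mRNA decay factor, fell by 3.07 and the helix-loop-helix factor ID2 fell by 2.58. The 3 that rose, named after their values were seen, were FOS, from 1.76 ± 0.113 to 6.90 ± 0.658 TPM (log2 change 1.51), EGR1 (0.63) and KLF10 (0.32). The KLF10 call was lost without vehicle replicate 1 (0.30) and without JMC45 replicate 1 (0.28), and its change was -0.12 with the mitochondrially encoded total held equal. The EGR1 call was also lost in that last setting (0.25). Camera did not call this list (adjusted p = 0.825) except without the filter on low values, where it lay below other genes (adjusted p = 0.0164).

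Transcripts of both survival and death factors had lower TPM. MCL1, an anti-apoptotic BCL2 family member, went from 134.4 ± 8.75 to 32.8 ± 2.98 TPM (log2 change -2.01, SE 0.09, limma adjusted p = 1.28e-05), and -0.68 after median-of-ratios scaling. All 9 tested anti-apoptotic genes fell on TPM, among them BCL2L2 (-2.03) and BCL2L1 (20.3 ± 0.106 and 4.35 ± 0.467 TPM), and after median-of-ratios scaling 5 fell and 2 rose. Of 19 pro-apoptotic genes 18 fell on TPM, and after median-of-ratios scaling 12 fell and 5 rose. DIABLO, which antagonises inhibitor of apoptosis proteins (-2.81) and BMF (-2.75) led them. Of 33 p53 target genes 22 fell on TPM and 2 rose, whereas after median-of-ratios scaling 7 fell and 17 rose. XPC (-2.38), a DNA damage sensor, and BTG2 (-2.25) had the largest decreases. The 2 that rose, named after their values were seen, were the cell cycle inhibitor CDKN1A, from 20.2 ± 0.00707 to 37.1 ± 3.89 TPM (0.84), and the secreted factor GDF15, from 12.0 ± 0.771 to 24.1 ± 2.51 TPM (0.94). Camera called none of these lists (adjusted p = 0.175, 0.175 and 0.170), but it placed the p53 list above other genes after quantile normalization (adjusted p = 0.0440) and the other 2 below them without the filter on low values (adjusted p = 0.00480 and 0.000660).

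**Figure D2:**
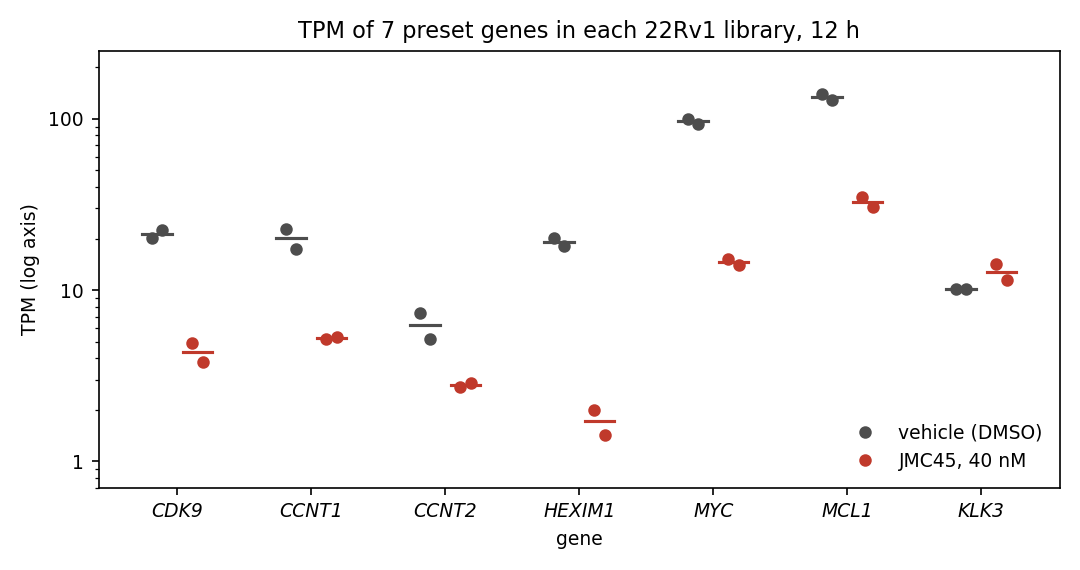
TPM (y axis, log scale) of 7 preset genes (x axis) in each library; points are libraries and horizontal lines are group means of 2 libraries. CDK9, CCNT1, HEXIM1, MYC and MCL1 are lower in both JMC45 libraries; CCNT2 is too, but its change becomes 0.16 after median-of-ratios scaling, and KLK3 is at 10.09 in both vehicle libraries and at 14.2 and 11.5 in JMC45, a change that becomes -0.11 with the mitochondrially encoded total held equal.

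KLK3, which encodes prostate-specific antigen, was at 10.09 TPM in both vehicle libraries and at 14.2 and 11.5 TPM in JMC45. Its change of 0.31 did not pass (adjusted p = 0.0576), although it did after median-of-ratios scaling (1.55), after quantile normalization (1.60), with the mitochondrially encoded genes left out (0.46), with the replicate block (adjusted p = 0.0473) and without JMC45 replicate 2 (0.46), and it was -0.11 with the mitochondrially encoded total held equal. Of 40 androgen-induced genes 34 fell on TPM and 1 rose, whereas after median-of-ratios scaling 11 fell and 17 rose. C1orf116 went from 69.6 ± 0.757 to 3.49 ± 0.276 TPM (log2 change -3.98), the epithelial transcription factor SPDEF fell by 2.92 and PLPP1 by 2.67. Of 10 androgen-repressed genes 6 fell on TPM, and after median-of-ratios scaling 3 fell and 5 rose. TMEFF2 (-2.47) and CAMK2N1 (-1.91) led them. Camera called neither list (adjusted p = 0.704 and 0.209), but it placed the androgen-induced genes below other genes without the filter on low values (adjusted p = 0.00480).

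Luminal epithelial markers lay below other genes. All 16 fell on TPM, with a median of -1.93, and after median-of-ratios scaling 10 fell and 4 rose. The keratin KRT19 went from 129.5 ± 2.57 to 11.5 ± 0.226 TPM (log2 change -3.39), the tight junction gene CLDN4 fell by 3.16 and the prostate homeobox gene HOXB13 by 3.10. Camera's call (adjusted p = 0.0111) had adjusted p = 0.516 with an estimated correlation and was lost under median-of-ratios scaling (adjusted p = 0.107). Of 7 neuroendocrine markers with enough signal 2 rose and 2 fell on TPM, and after median-of-ratios scaling 5 rose and 2 fell. EZH2 (-2.42) and ONECUT2 (-1.45) were those that fell, and the call of ONECUT2 was lost after quantile normalization (-0.24). SRRM4, a neural splicing factor, and the neuronal enolase ENO2 rose by 0.26 and 0.17, but neither passed when adjusted over the list alone and both were below 0 with the mitochondrially encoded total held equal (-0.18 and -0.28). The SRRM4 call was lost without vehicle replicate 2 (0.18) and without either JMC45 library (0.29 and 0.24), and the ENO2 call was lost without any 1 of the 4 libraries (0.16 to 0.19). Of 5 fibroblast markers 2 fell on TPM, and after median-of-ratios scaling 4 rose. VIM (51.7 ± 0.438 and 35.9 ± 1.66 TPM) and TAGLN (2.69 ± 0.233 and 1.65 TPM) fell by 0.52 and 0.47 on TPM and rose by 0.81 and 0.44 after median-of-ratios scaling and by 0.44 and 0.67 after quantile normalization, and the TAGLN call was lost without either JMC45 library. Camera placed these lists above other genes (adjusted p = 0.0111 and 0.0462), each with adjusted p = 0.516 with an estimated correlation, although the medians of both were below 0 (-0.01 and -0.33) and fry called both lower. Both camera calls were lost under median-of-ratios scaling (adjusted p = 0.107 and 0.0737). The neuroendocrine call was also lost after quantile normalization, without the filter on low values and with the mitochondrially encoded total held equal, and the fibroblast call with the mitochondrially encoded genes left out, without vehicle replicate 2 and without JMC45 replicate 2. Of the basal epithelial markers only 3 were tested, of which the most abundant was SNAI2 (15.2 ± 0.120 and 1.36 ± 0.339 TPM). No leukocyte or endothelial marker reached a mean TPM of 1, and the highest was FCER1G at 0.75.

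On TPM, cytosolic ribosomal proteins and mitochondrially encoded genes were the only lists with a median above 0, and the median of the latter was no longer above 0 after quantile normalization. Of 79 cytosolic ribosomal protein genes 69 rose, 70 adjusted over the list alone with 1 that fell, and the median was 0.55, and 79 rose after median-of-ratios scaling, but quantile normalization gave 33 that rose and 12 that fell. RPS29 went from 4198 ± 936 to 9025 ± 785 TPM (log2 change 1.12) and RPS12 from 2442 ± 287 to 5064 ± 334 TPM (1.06), values that are uncertain where reads are shared with ribosomal protein pseudogenes. Of 15 mitochondrially encoded genes 11 rose and 1 fell on TPM, whereas 15 rose after median-of-ratios scaling and 3 rose and 3 fell after quantile normalization. MT-CO1, a cytochrome oxidase subunit, went from 9497 ± 75.9 to 22630 ± 952 TPM (1.25), and the mitochondrial ribosomal RNA MT-RNR2 from 4500 ± 299 to 9376 ± 458 TPM (1.06). MT-ND2, singled out after its value was seen, fell by 0.40 on TPM and was 0.96 higher after median-of-ratios scaling. Of 77 nuclear oxidative phosphorylation genes 22 rose and 29 fell on TPM, 20 and 25 adjusted over the list alone, while after median-of-ratios scaling 74 rose and 1 fell. The complex I genes NDUFV3 (24.3 ± 1.82 and 5.33 ± 0.587 TPM) and NDUFA8 (log2 change -1.24, and 0.09 after median-of-ratios scaling) had the largest decreases. Camera placed the 3 lists above other genes (adjusted p = 3.78e-98, 1.55e-25 and 1.65e-17), with adjusted p = 0.474, 0.466 and 0.516 with an estimated correlation, and fry did not call the nuclear oxidative phosphorylation list (adjusted p = 0.0998). Camera did not match genes on abundance. The most abundant eighth of nuclear protein-coding genes also lay above the all-gene median, at -0.395 against -1.10. How far abundance accounts for the position of these lists was not tested. The camera call of the mitochondrially encoded list was lost after quantile normalization (adjusted p = 0.729).

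Small nucleolar RNA host genes split. Of 25, on TPM 8 rose and 14 fell, and after median-of-ratios scaling 14 rose and 9 fell. SNHG30 (-2.68) and SNHG26 (-2.52) had the largest decreases, and among those that rose SNHG19 went from 167.9 ± 17.7 to 330.9 ± 14.8 TPM (0.98) and GAS5 from 665.2 ± 60.9 to 1243 ± 39.1 TPM (0.90), the last 2 named after their values were seen. The list's median was -0.69, which is 0.41 above that of all genes. Of 30 replication-dependent histone genes 3 rose and 7 fell on TPM, 2 and 6 adjusted over the list alone, whereas after median-of-ratios scaling 19 rose and 1 fell. H4C1 fell by 1.87, a call lost after quantile normalization (-0.52), and H4C5 fell by 1.11, with 0.17 after quantile normalization and no call after median-of-ratios scaling or without JMC45 replicate 1. H4C3, H2BC5 and H2AC14 rose by 0.99, 0.88 and 0.80, the last with no call without vehicle replicate 1 or without JMC45 replicate 2. These are near-identical genes whose transcripts mostly lack poly(A) tails, so their values are uncertain. Camera placed both lists above other genes (adjusted p = 0.000232 and 8.55e-08), with adjusted p = 0.516 and 0.466 with an estimated correlation, while the medians of both were below 0 and fry called both lower (adjusted p = 0.00257 and 0.0172). The host gene call was lost under median-of-ratios scaling (adjusted p = 0.267), under quantile normalization (0.495) and without the filter on low values (0.312).

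The 10 largest increases were mostly short noncoding RNAs. The U1 small nuclear RNA variants RNVU1-6, RNVU1-26 and RNVU1-25 were listed at 0 in both vehicle libraries and averaged 175.0 ± 12.8, 107.3 ± 13.9 and 34.4 ± 2.59 TPM in JMC45. RNU1-2 and RNVU1-29 had identical values, 9.19 ± 8.82 TPM in vehicle and 230.6 ± 271 TPM in JMC45, and both calls were lost without vehicle replicate 1, without vehicle replicate 2 and without JMC45 replicate 2 (log2 changes 2.98, 5.04 and 2.31). The U3 small nucleolar RNAs SNORD3A and SNORD3B-2 rose by 4.21 and 3.85, RPPH1, the RNA of ribonuclease P, by 2.51, and LINC01551 by 3.38. TUBA1B-AS1 went from 92.6 ± 10.0 to 530.8 ± 46.5 TPM (2.51), a value that cannot be told apart from sense reads of its partner gene if strand was not used. Copies of U1 and U3 share sequence, and the division of reads among them is uncertain. The remaining large decreases were those of GPANK1, from 33.2 ± 0.0212 to 0.665 ± 0.0778 TPM (-4.36), the phosphatase-1 regulator PPP1R10, from 29.7 ± 3.92 to 0.505 ± 0.106 TPM (-4.35), and LINC00339, from 20.1 ± 1.24 to 0.540 ± 0.226 TPM (-3.78).

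Stress and inflammatory genes were mostly lower in TPM and were not called by camera as lists in the main setting. Of 31 genes of the integrated and ER stress responses 25 fell and 3 rose on TPM, whereas after median-of-ratios scaling 11 fell and 14 rose. The transcription factors DDIT3, from 73.5 ± 9.57 to 5.74 ± 0.354 TPM (log2 change -3.46), and XBP1 (-2.81) had the largest decreases, and TRIB3, PHGDH and SHMT2, named after their values were seen, changed by 0.34, 0.27 and 0.18. With the mitochondrially encoded total held equal these became -0.11, -0.19 and -0.28, and the PHGDH call was lost without vehicle replicate 2 (0.23) and that of SHMT2 without any 1 of the 4 libraries (0.15 to 0.20). Of 21 heat shock genes 19 fell on TPM, with DNAJB1 at -3.17 and HSF2 at -3.01, and after median-of-ratios scaling 8 fell and 8 rose. Of 9 NF-kB target genes 8 fell, among them the inhibitor NFKBIA (-3.38) and NFKB2 (-2.22), and after median-of-ratios scaling 7 fell and 1 rose. Of 18 interferon-stimulated genes 14 fell on TPM, led by USP18 (-1.86) and IFIH1 (-1.38, a call lost after quantile normalization), and after median-of-ratios scaling 4 fell and 5 rose. The adjusted p-values of camera were 0.704, 0.0711, 0.735 and 0.959 for these 4 lists. Camera did place the heat shock list below other genes after quantile normalization (adjusted p = 0.00172) and, like the stress response list, without the filter on low values (0.000166 and 0.00362).

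Metabolic lists were mixed. Of 24 cholesterol synthesis genes 14 fell and 4 rose on TPM, with 3 that rose adjusted over the list alone, whereas after median-of-ratios scaling 3 fell and 16 rose. The epoxidase SQLE (-2.20) and MVK (-2.17) had the largest decreases. Of those that rose, 3 named after their values were seen were LSS, from 23.03 ± 0.523 to 40.9 ± 0.587 TPM (0.80), MVD (0.53, not called without vehicle replicate 1, 0.49) and SREBF2 (0.21, not called without vehicle replicate 1, without vehicle replicate 2 or without JMC45 replicate 2, and -0.25 with the mitochondrially encoded total held equal). Of 29 lysosome and autophagy genes 20 fell on TPM and 4 rose, whereas after median-of-ratios scaling 7 fell and 19 rose. The autophagy kinase ULK1 fell by 2.08. NPC2, LAMP1, CTSB and CTSD, all 4 named after their values were seen, rose by 0.62, 0.36, 0.32 and 0.24. With the mitochondrially encoded total held equal the NPC2 call was lost (0.16), and the others had values of -0.09, -0.13 and -0.21. The CTSD call was lost without vehicle replicate 1, without vehicle replicate 2 and without JMC45 replicate 1. Camera placed this list above other genes (adjusted p = 0.0127), with adjusted p = 0.531 with an estimated correlation, although its median was -0.42 and fry called it lower (adjusted p = 0.00312). The camera call was lost with the mitochondrially encoded total held equal (adjusted p = 0.283) and without the filter on low values (0.975). Of 29 hypoxia and glycolysis genes 18 fell on TPM and 2 rose, 1 of them adjusted over the list alone, whereas after median-of-ratios scaling 6 fell and 18 rose. The glucose transporter SLC2A1 went from 30.8 ± 0.304 to 1.59 ± 0.248 TPM (-3.62) and the oxygen sensor EGLN1 fell by 2.60, while ENO2 and PFKL, the latter named after its value was seen, rose by 0.17 and 0.19. The PFKL call was lost without any 1 of the 4 libraries (0.15 to 0.23), and its change was -0.26 with the mitochondrially encoded total held equal. Of 20 NRF2 target genes 14 fell on TPM, led by GCLC, which makes a glutathione precursor (-3.28), and SRXN1 (-1.52, a call lost after median-of-ratios scaling, at -0.23), and after median-of-ratios scaling 3 fell and 10 rose. The ferritin genes FTH1 and FTL, named after their values were seen, rose by 0.42 and 0.32 on TPM and had values of -0.04 and -0.14 with the mitochondrially encoded total held equal, and the FTL call was lost without vehicle replicate 1 (adjusted p = 0.0503). Camera called none of the cholesterol, hypoxia and NRF2 lists (adjusted p = 0.0639, 0.175 and 0.310), but after median-of-ratios scaling it placed the first 2 above other genes (adjusted p = 0.00713 and 0.0199), as it did with the mitochondrially encoded genes left out (0.0219 for both). It also called the cholesterol list at a mean TPM of at least 5, without the intensity trend and without vehicle replicate 1.

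**Figure D3:**
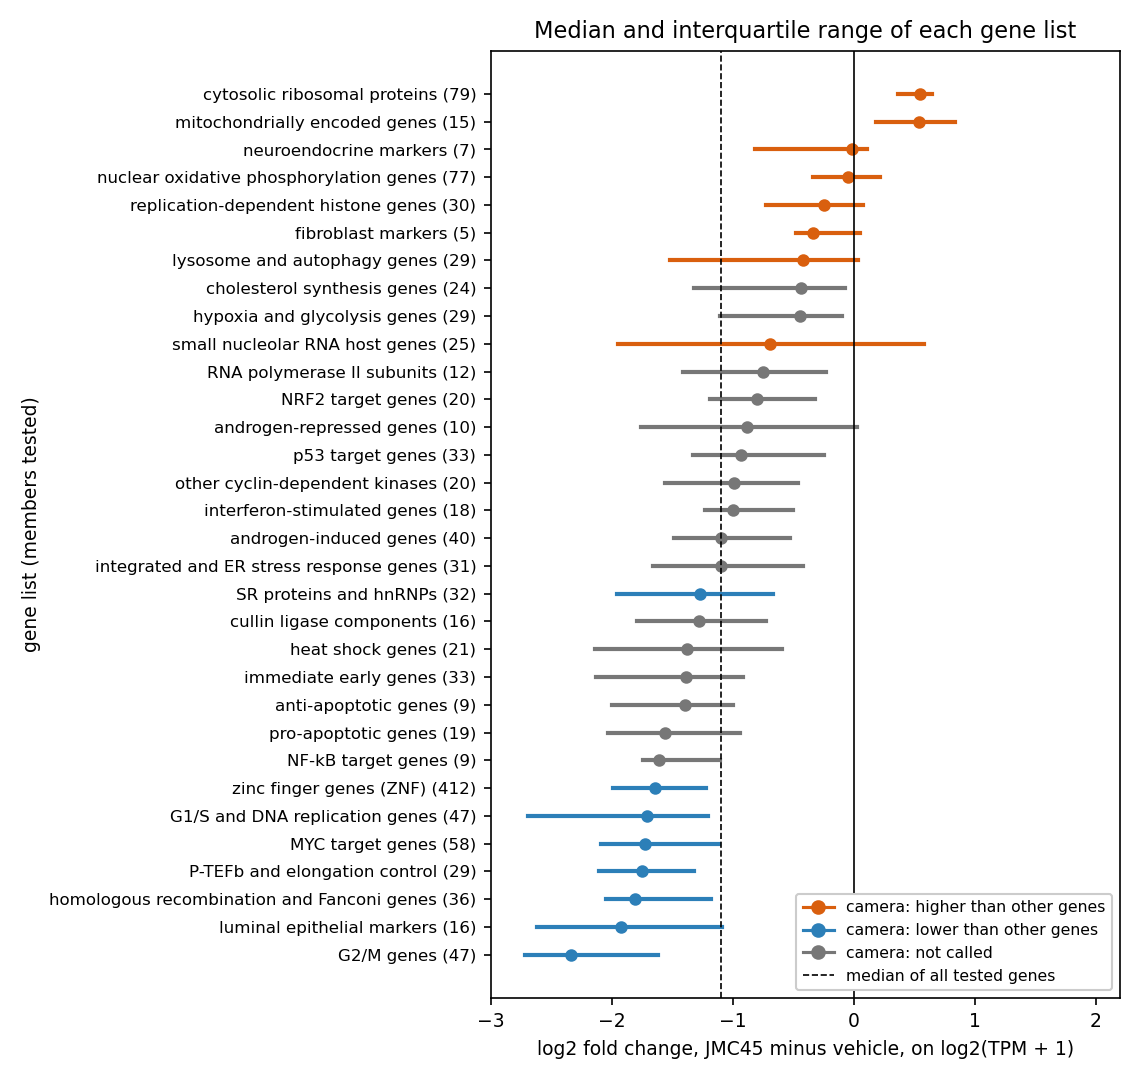
Median (point) and interquartile range (bar) of the log2 fold change (x axis, JMC45 minus vehicle on log2(TPM + 1)) of the tested members of each gene list (y axis), coloured by the camera call at the preset correlation. The dashed line is the all-gene median of -1.10; G2/M genes lie lowest, at -2.34, and ribosomal protein genes highest, at 0.55, or 0.11 after quantile normalization.

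Over the 32 lists, camera called 8 higher and 8 lower than other genes at the preset correlation, and with an estimated correlation it called 0, the smallest adjusted p being 0.466. That loss does not by itself show that list members vary together. Lists with an estimated correlation under the preset one, such as the MYC target list (0.00205), lost their calls as well. In the simulation, whose noise was independent between genes, camera's p for the shifted list likewise went from 1.8e-92 to 0.0017. A weaker result thus arose there without correlated noise. Fry called 29 lists lower, 2 higher and 1 neither. In 25 lists the numbers that rose and fell were the same adjusted over the list alone as over all genes, and the 7 others are given with their lists. No list was compared with genes of like TPM. Changes differed with abundance, so the position of any list relative to all genes may partly reflect the TPM of its members.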

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

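The setting in which the mitochondrially encoded total was held equal was chosen after the result was seen, and all others were planned. Scaling decided the direction of the typical gene. Median-of-ratios scaling gave 4888 genes higher, 4981 lower, 1973 at least 2-fold higher and 2042 at least 2-fold lower, quantile normalization gave 4716, 4603, 1381 and 1552, and holding the mitochondrially encoded total equal gave 181 genes higher. The first 2 centre the typical gene near 0 by construction. With a mean TPM of at least 5, 58 genes were at least 2-fold higher and 5008 at least 2-fold lower, with 9110 genes tested. Leaving out 1 library at a time gave 425 to 530 genes higher, 10513 to 11083 lower, 119 to 145 at least 2-fold higher and 7185 to 7967 at least 2-fold lower, with the lone library of a group assumed to vary like the others. CDK9 stayed lower and past the threshold under every setting, from -2.47 to -0.72, with adjusted p up to 0.00691. The number of lists below other genes was 17 without the filter on low values, where 31100 genes with a median change of -0.30 were tested, the 9 gained being not called otherwise but for the heat shock list after quantile normalization, and 0 with an estimated correlation, as was the number of lists above; the cause was not tested. The mitochondrially encoded list turned to -0.018 relative to all genes after quantile normalization, which forces the most abundant genes to one distribution, and the list of SR proteins and hnRNPs turned to 0.087 after median-of-ratios scaling.

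Of the other 126 named genes, direction turned after median-of-ratios scaling for CCNT2 (0.16), MT-ND2 (0.96), NDUFA8 (0.0932), VIM (0.81) and TAGLN (0.44), and after quantile normalization for CCNT2 (0.40), H4C5 (0.17), VIM (0.44) and TAGLN (0.67). With the mitochondrially encoded total held equal it turned for KLK3 (-0.11), KLF10 (-0.12), FANCA (-0.13), TRIB3 (-0.11), PHGDH (-0.19), SHMT2 (-0.28), SREBF2 (-0.25), FTH1 (-0.0393), FTL (-0.14), PFKL (-0.26), ENO2 (-0.28), SRRM4 (-0.18), LAMP1 (-0.0934), CTSB (-0.13) and CTSD (-0.21), and the calls of EGR1 (0.25), NPC2 (0.16), MVD (0.07) and H2AC14 (0.47) were lost. Without the filter on low values the calls of RNU1-2, RNVU1-29, FANCA, PFKL, SRRM4, TAGLN, CTSD and H2AC14 were lost, without the intensity trend those of FANCA, SHMT2, SREBF2, PFKL, ENO2, SRRM4 and CTSD, and under the replicate block those of SHMT2, PFKL and ENO2. The samples share only a replicate number: the deviations of same-numbered libraries correlated at -0.047, and the replicate block gave 613 genes higher and 11380 lower. The unknown depth limits what can be said of genes with low TPM.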

Other observations

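All tests in this part but that of expression level and exonic length for single-exon genes were chosen after the result was seen. Among nuclear protein-coding genes that rose, the largest increases outside the lists at a mean TPM of at least 5 were those of PDIA2, a disulfide isomerase, from 1.55 ± 0.686 to 9.15 ± 1.29 TPM (log2 change 2.02), SCD, the fatty acid desaturase, from 84.3 ± 2.92 to 203.4 ± 15.6 TPM (1.26), and the secretoglobin SCGB1D2, from 10.8 ± 0.410 to 26.2 ± 1.03 TPM (1.21). The calcium-binding protein gene S100P rose by 0.97 and FASN, fatty acid synthase, by 0.89. All 5 also rose after median-of-ratios scaling, which raises the changes of genes in general. Their lowest changes in any setting were 1.67, 0.80, 0.78, 0.51 and 0.43, in the order named. They were named after their values were seen, from a list of 12 ordered by change.

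The first pattern is the lower TPM of most genes. One common scaling factor from the TPM normalization would alone leave the changes of abundant genes near the replicate noise. On the log2(TPM + 1) scale it would spread those of genes with low TPM. The interquartile range of changes was 1.18 over all tested genes, against 0.246 for the wider of the replicate differences. Over 997 genes with a mean TPM of at least 100, where that scale matters little, it was 0.836 against 0.137. One factor alone would not give that spread. Lower depth in the JMC45 libraries would leave abundant genes at that noise. Over the 997 genes with a mean TPM of at least 100, however, the range was 0.836 against 0.137. Their median was -0.23, and that of the other genes was lower by a difference of -0.934. The least abundant eighth of nuclear protein-coding genes (-0.95) lay above the next 5 (-1.45 to -1.22). Lower depth would also widen the differences between the JMC45 libraries rather than lower a share. The median absolute log2 difference was 0.116 between the JMC45 libraries, against 0.135 between the vehicle libraries. Those differences were taken over all tested genes, not by abundance. The log2(TPM + 1) scale also narrows differences at low TPM, and most genes had lower TPM in JMC45. The same scale limits the change of the least abundant eighth. These values therefore cannot decide on depth, which stays open for genes under a mean TPM of 100. RNA degradation that removes long transcripts stays open too, since the eighth of nuclear protein-coding genes with the shortest exonic length lay 0.253 above the longest eighth (-0.86 and -1.11), although the 6 between (-1.21 to -1.14) all lay below the longest, a test that took the place of a rank correlation with exonic length (-0.082) and of a cut-off on the shortest eighth after their results were seen. The common part of the shift (-1.10 on TPM and -0.02 after median-of-ratios scaling) cannot be placed without a spike-in, and an effect of the treatment stays open beside these.

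The second pattern is a rise of the small RNAs U1, U2 and U3, which normally lack poly(A) tails. Summed over copies, U1 went from 92.3 ± 93.0 to 976.7 ± 409 TPM, U2 from 21.7 ± 16.7 to 546.1 ± 44.2 TPM and U3 from 10.8 ± 6.47 to 74.1 ± 17.7 TPM, while 7SL went from 375.7 ± 2.40 to 663.3 ± 60.5 TPM, RMRP, at 9.25 ± 7.55 and 24.6 ± 18.4 TPM, overlapped between groups, and the share of histone transcripts was lower on TPM. Reads moved between identical gene copies would leave the sums alone, but the smallest gap between any JMC45 and any vehicle library was 1.94 on the log2 scale. Uniform carry-over of RNA without poly(A) tails would raise 7SL as much, but the smallest rise of U1, U2 or U3 exceeded the largest rise of 7SL (0.915) by 1.02. That comparison rests on 7SL alone, which did not follow U1 within the vehicle group. In vehicle replicates 1 and 2, 7SL was at 373.97 and 377.36 TPM, while U1 was at 26.55 and 158.06 TPM. The comparison therefore argues only against a rise that 7SL shares equally. RPPH1 (7.73-fold), BCYRN1 (3.79-fold) and 7SK (2.98-fold) were also higher in each JMC45 library than in each vehicle library, so a rise of such RNAs in general that is not uniform stays open, as do an altered 3' end, which was not tested, size selection and the short length of these genes.

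The third pattern is a larger decrease of intronless genes. The 161 single-exon protein-coding genes had a median change of -1.93, against -1.12 for 11396 multi-exon genes, although the numbers that fell, 138 and 9544, were similar as shares. The larger decrease was not particular to intronless genes. The 1693 genes with 1 to 4 exons, of which these are a small part, had a median of -1.54. The medians of the bins with more exons ran from -1.11 to -1.02. If expression level and exonic length accounted for this, multi-exon genes matched on both would fall as much, but the single-exon median was lower than that of 10000 matched lists by a log2 difference of -0.80, and the middle 95% of the lists ran from -1.34 to -0.97. A shorter lifetime of these transcripts may account for the difference, as a hypothesis that was not tested.

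By genomic span, the eighth of nuclear protein-coding genes with the longest span had a median of -0.93, against -1.09 for the shortest eighth. The eighths between ran from -1.23 to -1.15, all below both ends, so there was no steady trend with span. The noncoding RNA BCYRN1 rose from 223.5 ± 11.2 to 845.9 ± 122 TPM, and it derives from an Alu repeat, so its reads are uncertain. The annotated 7SK gene RN7SK rose by 1.43, a call lost without vehicle replicate 2 (1.19).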
